A study of Lolium multiflorum with 4 samples.

How the data were processed

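RNA was sequenced from seedlings of Lolium multiflorum (Italian ryegrass) labelled LmHC for high cadmium and LmLC for low cadmium. These were read as 2 plant lines, because the series design and the growth protocol name them as separate seed material. The sample labels, however, carry high and low cadmium under a treatment tag, and they add earlier names (Dg and Vm) without explanation. Every comparison of LmHC with LmLC rests on this reading. Each line was sampled at 0 h and after 24 h with 300 µM cadmium chloride, so there were 4 groups of 1 library each. Per the labels' protocols, seedlings were moved from agar to a nutrient solution at 7 days, treatment began at an age of 2 weeks, total RNA was extracted from plant tissue that is not specified further, and polyadenylated RNA was captured with oligo(dT) beads before cDNA synthesis with random hexamers. The labels do not say how many seedlings went into a library, nor whether high and low cadmium refer to uptake, accumulation or tolerance.

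The deposited table holds FPKM values, fragments per kilobase of contig scaled to the mapped fragments of the library, for 111761 contigs in 4 columns, rounded by the authors to 2 decimals. Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM 1.2.8 were used. The assembler, its settings, the contig lengths and any filter are not given in the sources used here. Contig names follow an assembly: 61184 contigs carry the name of 1 of 15237 clusters, and 50577 stand alone. RSEM divides fragments that fit several contigs among them, so values of contigs in 1 cluster, which may be alleles, splice forms or gene copies, depend on each other. The table does not pair contigs with gene names, and no reference was used here. The lists of transporter, metal-binding, sulfur, stress and photosynthesis genes that had been fixed before the data were examined could therefore not be applied, and contigs are given by their names in the table.

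Because each group had 1 library, the comparisons within a line, between the lines at 1 time and of the responses leave no residual degrees of freedom, and no p-value, standard error or replicate spread is given. An additive model of line and time over the 4 libraries would leave 1 residual degree of freedom by taking any difference between the lines' responses as error. It was not planned and was not run. A fixed rule of size was used instead, chosen before the data were examined. A contig was taken as expressed if its mean FPKM over the 4 libraries was at least 1, which left 70885 contigs. Ratios were computed as log2 of (FPKM + 1) in one library over (FPKM + 1) in the other, which understates the change of low contigs, and a contig was counted as higher or lower when this ratio reached 2-fold, a log2 of at least 1 in size. Changes after 24 h, differences between the lines at each time, and the difference of the lines' log2 changes were counted in this way. The named contigs are the 2 with the largest and the 2 with the smallest ratio in each comparison. Where a library is listed at 0, the levels are given without a fold.

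The files give no fragment counts. The relative depth of the libraries was estimated from low values, since contigs with the same small number of fragments in 2 libraries share 1 ratio of FPKM. Among stand-alone contigs between 0.3 and 1.2 FPKM in both libraries, the most frequent log2 ratio (counted within 0.02 on either side) was taken as the worth of 1 fragment in one library over the other. The search covered only ratios well within 2-fold of equal depth, so it could not return a 2-fold difference in depth. The estimate also assumes that fragment lengths were alike. The absolute depth is unknown, so no counting interval can be given.

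Alternatives tried were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, scaling to the same column total, scaling by the median of ratios to the geometric mean over contigs above 0 in all 4 libraries, and summing contigs of a cluster. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The counting rule was tested on simulated data for all 111761 contigs with assumed contig lengths and depths: of 50 contigs made 3-fold higher, 50 were called in each line, of 50 made 3-fold lower, 45 were called in LmHC and 47 in LmLC, and all 50 made 8-fold higher and all 50 made 8-fold lower were called in both lines. Of 59274 unchanged contigs, 0.11% were called for LmHC and 0.13% for LmLC in the 24 h comparisons. The contigs made higher or lower were drawn only from those with a mean of at least 5 FPKM at 0 h. Recovery of changes in lower contigs was therefore not tested, and 43916 of the expressed contigs had a mean of 1 to 5 FPKM over the 4 libraries. The simulation held counting error alone and no variation between plants.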

Results

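Transcript abundance was measured in 4 libraries of Lolium multiflorum, a forage grass. LmHC and LmLC, read as 2 lines although the sample labels list high and low cadmium as a treatment, were each sequenced before treatment (0 h) and after 24 h in 300 µM cadmium chloride. Cadmium is a metal toxic to plants. The series asks which genes, cadmium transporters among them, differ between the lines in expression or in response. Contigs could not be matched to gene names here, so the comparisons below concern contigs and assembly clusters and not named transporters. The column totals were alike, from 782476 FPKM in LmHC at 24 h to 795368 FPKM in LmLC at 24 h. Relative depth was estimated from low values, in a search that covered only ratios well within 2-fold. Relative to its 0 h library, the 24 h library had an estimated depth of 0.956 in LmHC and 0.92 in LmLC. LmHC had an estimated depth of 0.99 relative to LmLC at 0 h and of 1.028 at 24 h.

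More contigs reached 1 FPKM at 24 h than at 0 h in both lines, but fewer reached 10 FPKM. In LmHC, 57526 contigs reached 1 FPKM at 0 h and 64970 at 24 h, and in LmLC the numbers were 58625 and 67654. At 10 FPKM or more, the numbers at 0 h and 24 h were 14852 and 14135 in LmHC, and 14691 and 14521 in LmLC. Contigs listed at 0 numbered 24679 in LmHC and 22353 in LmLC at 0 h, and 17523 and 14788 at 24 h. The most abundant transcripts were largely exchanged: of the 100 contigs with the highest FPKM at 0 h, 24 were also among the top 100 at 24 h in LmHC and 23 in LmLC. Between the lines, 88 of the top 100 were shared at 0 h and 84 at 24 h.

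The first comparison asks what changed in LmHC between 0 h and 24 h of cadmium. Of 70885 expressed contigs, 20018 (28.2%) were at least 2-fold higher at 24 h and 19536 (27.6%) at least 2-fold lower. The 55.8% at least 2-fold apart became 67.9% with a pseudocount of 0.1, 20.0% with a pseudocount of 5 and 60.6% at a mean of at least 5 FPKM. Large increases outnumbered large decreases, with 3086 contigs at least 8-fold higher and 222 at least 8-fold lower, or 10922 and 2232 with a pseudocount of 0.1. The largest increases were in CL3835.Contig11_All, from 0.24 to 632.09 FPKM (log2 ratio 9.0), and Unigene20305_All, from 0.14 to 569.27 FPKM (log2 ratio 8.97). The largest decreases were in CL525.Contig16_All, at 48.43 FPKM at 0 h and listed at 0 at 24 h, and Unigene31524_All, at 42.44 FPKM at 0 h and listed at 0 at 24 h. There was no replicate check on these differences, and cadmium and the passage of 24 h cannot be told apart, since no untreated 24 h library was analysed here. The balance of higher and lower contigs past 2-fold depended on the setting: median-of-ratios scaling moved the median log2 ratio of expressed contigs from -0.20 to 0.08, and the share of higher contigs among those at least 2-fold apart from 50.6% to 68.3%, with 4082 contigs at least 8-fold higher and 109 at least 8-fold lower, whereas at a mean of at least 5 FPKM 6984 contigs were higher and 9356 lower.

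The same comparison in LmLC gave 20736 contigs (29.3%) at least 2-fold higher and 17614 (24.8%) at least 2-fold lower at 24 h. The 54.1% at least 2-fold apart became 66.4% with a pseudocount of 0.1, 19.6% with a pseudocount of 5 and 58.0% at a mean of at least 5 FPKM. At least 8-fold, 3128 contigs were higher and 265 lower, or 11257 and 2251 with a pseudocount of 0.1. The contigs with the largest increases were those of LmHC: Unigene20305_All went from 0.30 to 568.85 FPKM (log2 ratio 8.78) and CL3835.Contig11_All from 0.66 to 396.48 FPKM (log2 ratio 7.90). The largest decreases were in contigs seen in 1 library alone: CL12486.Contig2_All had 82.08 FPKM and Unigene38196_All 47.06 FPKM in LmLC at 0 h, and both were listed at 0 in the other libraries. Median-of-ratios scaling moved the median log2 ratio from -0.14 to 0.15 and the share of higher contigs among those at least 2-fold apart from 54.1% to 67.2%, and at a mean of at least 5 FPKM 7228 contigs were higher and 8405 lower.

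The lines' changes were alike across contigs. The log2 ratios of the lines, which share no library, correlated with a Pearson's r of 0.87 and a Spearman's rho of 0.86 across 70885 contigs, which are not independent replicates. At least 2-fold in both lines, 16533 contigs were higher and 12716 lower, against 5856 and 4854 for independent lists of these sizes. The 29249 contigs with a shared direction became 38366 with a pseudocount of 0.1 and 9716 with a pseudocount of 5. At a mean of at least 5 FPKM, 13201 of 26969 contigs shared a direction, with a Spearman's rho of 0.91. Of the 70885 contigs, 82 changed in opposite directions, against 10689 for independent lists. A further 3431 contigs were at least 2-fold higher in LmHC but not past 2-fold in LmLC, and 4175 the other way around. Among contigs lower at 24 h, 6792 passed 2-fold in LmHC alone and 4844 in LmLC alone. Passing the 2-fold limit in 1 line alone does not in itself show a difference between the lines.

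**Figure D1:**
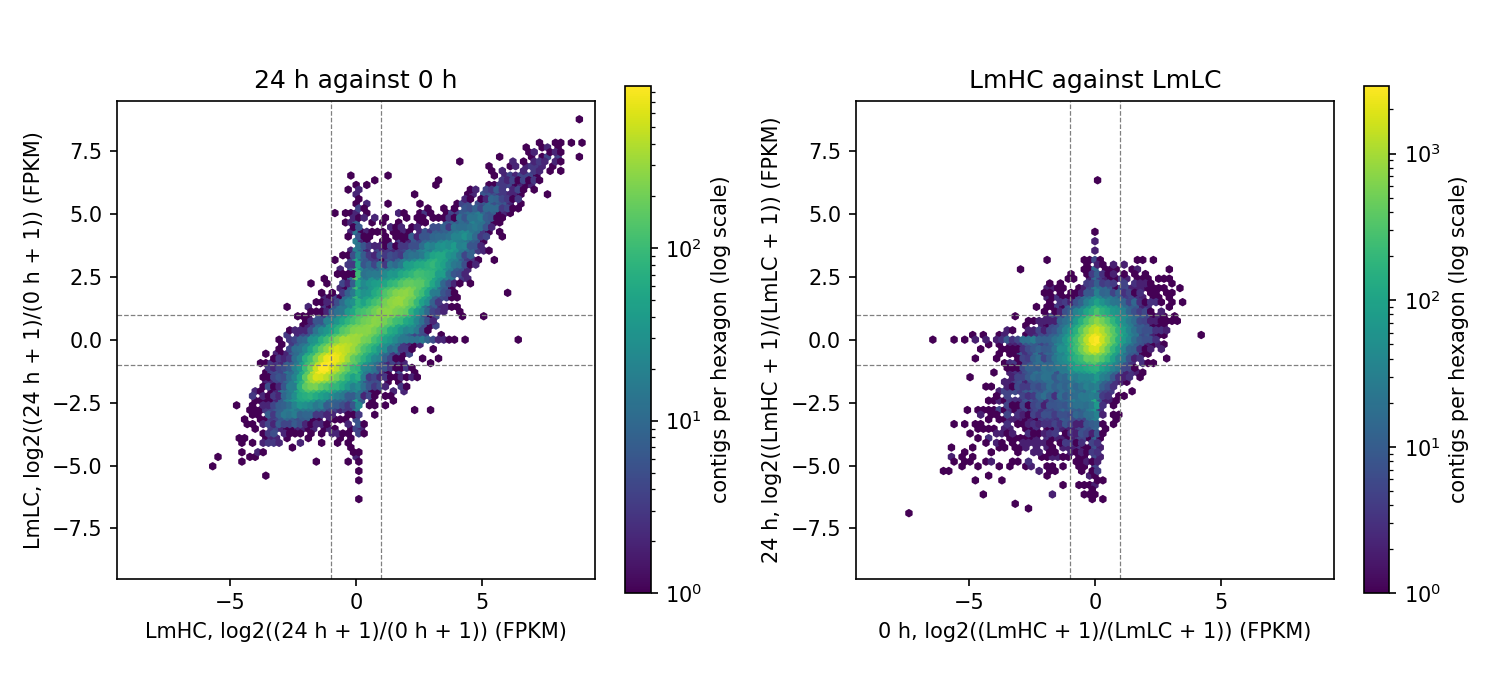
Hexagon density plots of expressed contigs, coloured by the number of contigs per hexagon on a log scale, with dashed lines at 2-fold. The left panel plots the log2 ratio of 24 h over 0 h in LmHC (horizontal) against LmLC (vertical), where the contigs lie along the diagonal (Pearson's r = 0.87). The right panel plots the log2 ratio of LmHC over LmLC at 0 h (horizontal) against 24 h (vertical), where the values spread farther below 0 than above it.

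At 0 h, before treatment, 1761 contigs (2.5%) were at least 2-fold higher in LmHC and 3139 (4.4%) at least 2-fold higher in LmLC, and 65985 were within 2-fold. The 6.9% of contigs at least 2-fold apart became 18.6% with a pseudocount of 0.1 and 1.3% with a pseudocount of 5. The standard deviation of the log2 ratio across contigs was 0.59 between the lines at 0 h, against 1.55 between the times in LmHC and 1.54 in LmLC. At least 8-fold, 8 contigs were higher in LmHC and 249 in LmLC, with 308 and 1689 at a pseudocount of 0.1, 2 and 116 at a mean of at least 5 FPKM, and 4 and 203 with median-of-ratios scaling. The largest ratios toward LmHC were those of Unigene5633_All, at 20.04 FPKM in LmHC and 0.17 FPKM in LmLC (log2 ratio 4.17), and CL7050.Contig1_All, at 10.25 and 0.01 FPKM (log2 ratio 3.48). The largest toward LmLC were Unigene36241_All, at 173.03 FPKM in LmLC and listed at 0 in LmHC, and CL12486.Contig2_All, with the values given above.

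At 24 h, 3158 contigs (4.5%) were at least 2-fold higher in LmHC and 5056 (7.1%) in LmLC, with a standard deviation of the log2 ratio of 0.76. The share at least 2-fold apart was 11.6%, and it was 22.3% with a pseudocount of 0.1 and 2.8% with a pseudocount of 5. At least 8-fold, 22 contigs were higher in LmHC and 596 in LmLC, with 501 and 2477 at a pseudocount of 0.1, 4 and 235 at a mean of at least 5 FPKM, and 39 and 676 with median-of-ratios scaling. Unigene35023_All had 82.82 FPKM and CL4549.Contig1_All 19.11 FPKM in LmHC at 24 h, and both were listed at 0 in the other libraries. Toward LmLC, Unigene36241_All had 124.29 FPKM in LmLC against 0.12 in LmHC (log2 ratio -6.81), and CL1972.Contig3_All had 105.63 FPKM in LmLC and was listed at 0 in both LmHC libraries. With 1 library of each line at each time, differences between lines cannot be told apart from differences between the plants or library preparations.

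The share of contigs at least 2-fold apart between the lines depended on the level. At 0 h it was 8.8% for a mean of 1 to 5 FPKM, 4.5% for 5 to 20, 2.4% for 20 to 100 and 0.7% above that. At 24 h it was 14.4%, 7.9%, 4.5% and 2.9%. The share at least 2-fold apart between the times did not decline with the level: in LmHC it was 52.9%, 60.3%, 61.1% and 61.8%, and in LmLC 51.7%, 57.1%, 59.4% and 65.1%.

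**Figure D2:**
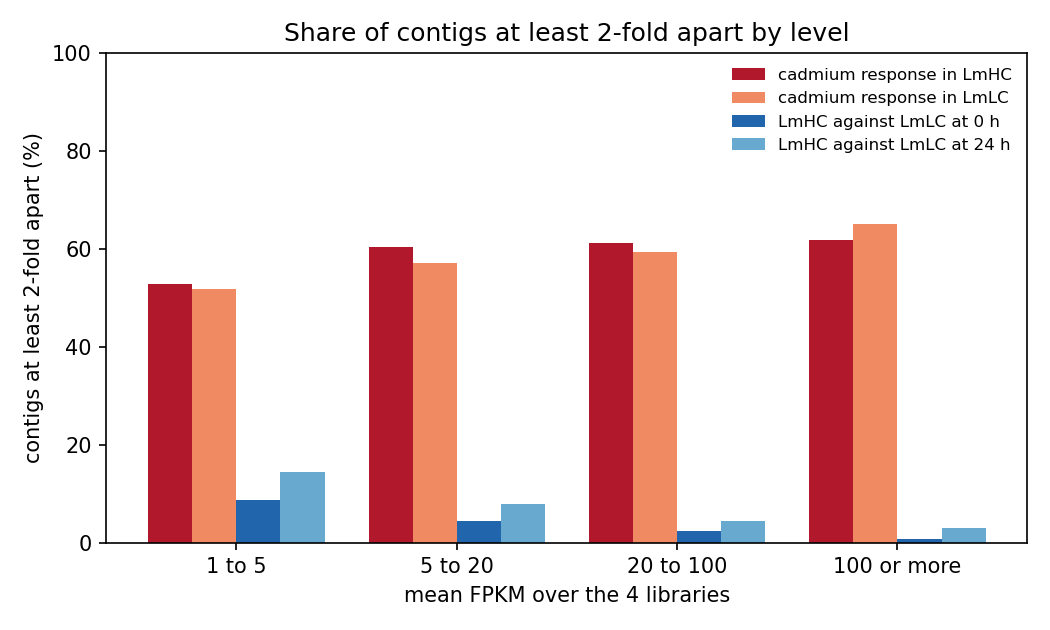
Bars give the percentage of expressed contigs at least 2-fold apart (vertical, 0 to 100%) in 4 classes of mean FPKM (horizontal) for the change at 24 h in each line and for the lines at each time, with 1 library per group and no error bars. The share between times is between 51.7% and 65.1% in every class, and the share between lines goes from 8.8% to 0.7% at 0 h and from 14.4% to 2.9% at 24 h.

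Line differences seen at both times were mostly toward LmLC. At least 2-fold at both times, 1463 contigs were higher in LmLC and 292 higher in LmHC, against 224 and 78 for independent lists, and 109 went in opposite directions, against 265. The 1755 contigs with a shared direction became 4821 with a pseudocount of 0.1 and 253 with a pseudocount of 5. Across contigs, the log2 ratio of the lines at 0 h and at 24 h correlated with a Pearson's r of 0.36 and a Spearman's rho of 0.24. Contigs listed at 0 in both libraries of a line and at 1 FPKM or more in both libraries of the other numbered 683 for LmLC and 16 for LmHC. At 2 FPKM or more these numbers were 324 and 4. Of 14852 contigs with at least 10 FPKM in LmHC at 0 h, 3 lay under 5% of that level in LmLC, whereas 163 of 14691 such contigs of LmLC lay under 5% in LmHC. At 24 h the numbers were 7 of 14135 and 379 of 14521.

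**Figure D3:**
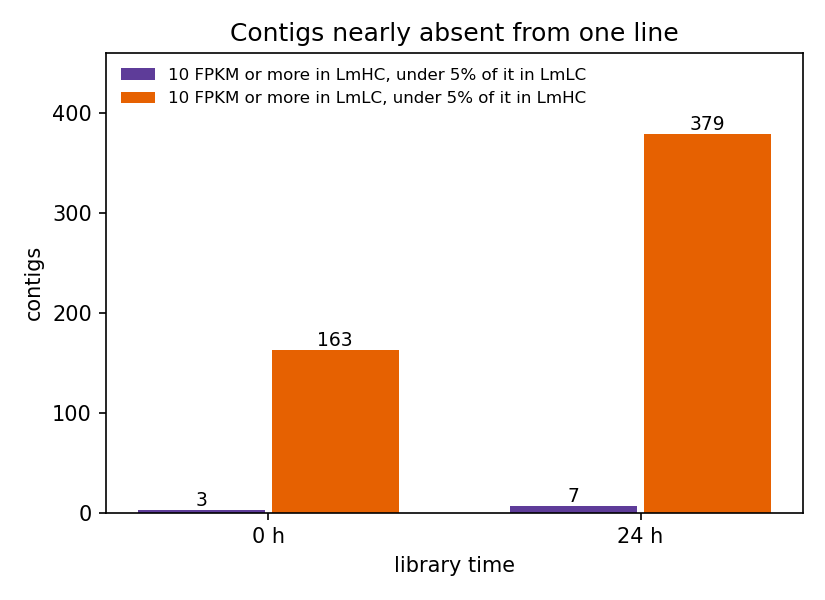
Bars count contigs (vertical) with at least 10 FPKM in one line and under 5% of that level in the other, at 0 h and 24 h (horizontal), with 1 library per bar pair and line. Contigs nearly absent from LmHC numbered 163 at 0 h and 379 at 24 h, and contigs nearly absent from LmLC numbered 3 and 7.

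The last comparison asks which contigs responded differently in the lines, by subtracting the log2 change in LmLC from that in LmHC. The difference was at least 2-fold toward LmHC for 4747 contigs (6.7%) and toward LmLC for 5757 (8.1%), with 9345 and 10567 at a pseudocount of 0.1 and 685 and 1388 at a pseudocount of 5. This 2-fold balance turned under median-of-ratios scaling, with 5730 toward LmHC and 5154 toward LmLC. The 8-fold balance did not turn. At least 8-fold, 98 differences were toward LmHC and 295 toward LmLC, and 106 and 340 with median-of-ratios scaling. They were 1040 and 1629 at a pseudocount of 0.1, and 26 and 104 at a mean of at least 5 FPKM. The largest differences toward LmHC were in Unigene35023_All, described above, and in CL12486.Contig2_All, whose value comes from its level in LmLC at 0 h. Toward LmLC, both largest differences were in a single assembly cluster. CL12723.Contig3_All went from 0.28 to 111.54 FPKM in LmLC (log2 ratio 6.46) and from 0.60 to 0.39 FPKM in LmHC (log2 ratio -0.20). CL12723.Contig2_All went from 0.29 to 76.94 FPKM in LmLC (log2 ratio 5.92), and had 0.27 FPKM at 0 h and was listed at 0 at 24 h in LmHC. This difference combines 4 libraries without replicates, so it carries the error of each.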

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

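The tests in this part were chosen after the results were seen, except the search for cluster partners of contigs that appeared at 24 h. Changes in opposite directions were found for 82 contigs: 54 were at least 2-fold higher at 24 h in LmHC and at least 2-fold lower in LmLC, and 28 were lower in LmHC and higher in LmLC. They were picked out because the single sample pair of each line moved the opposite way, and the difference was not tested.

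The first pattern is the one-sided set of line-specific contigs, 683 seen at both times in LmLC alone against 16 in LmHC alone. Assembly from LmLC reads alone is argued against by 719 contigs at 1 FPKM or more in an LmHC library and at 0 in both LmLC libraries. The rule for these is looser than for the 683 and 16, since 1 LmHC library was enough. Among them, 90 were above 0 only in LmHC at 0 h and 391 only in LmHC at 24 h. Because RSEM divides shared fragments, a contig listed at 0 need not lack fragments that fit it. The count of 719 does not address an assembly that drew on both lines unequally, which was not tested. Another organism in the LmLC material was examined through the clusters. In 286 of their 322 clusters (88.8%), the other contigs summed to at least 1 FPKM in each LmHC library. For these clusters, this argues against an organism whose contigs form clusters of their own. It cannot exclude a related organism whose contigs join ryegrass clusters, and the share among all clusters was not computed. Another organism stays open for the remaining clusters and for the 326 contigs outside clusters, which no value in the table assigns to an organism. LmHC RNA or LmHC-type plants within the LmLC libraries remain open, since 10 contigs of at least 10 FPKM in LmHC, both times summed, lay under 5% of that level in LmLC, and a mixture would leave few; under 10% of that level, 12 did at 0 h and 17 at 24 h, against 184 and 446 the other way around. Alleles or gene copies of ryegrass that LmLC holds and LmHC lacks may give the same values and could not be separated from a mixture here.

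The second pattern is the size of the change, with 55.8% of expressed contigs in LmHC and 54.1% in LmLC at least 2-fold apart between 0 h and 24 h. These shares were 67.9% and 66.4% with a pseudocount of 0.1, and 20.0% and 19.6% with a pseudocount of 5. At a mean of at least 5 FPKM they were 60.6% and 58.0%. For a difference in depth, the worth of 1 fragment had a log2 ratio between 24 h and 0 h of at most 0.12. The search covered only ratios well within 2-fold and could not have returned a 2-fold difference, so it cannot decide. FPKM is scaled to the mapped fragments, so a depth difference would act through counting error, mostly in low contigs. The share at least 2-fold apart was 52.9% in LmHC and 51.7% in LmLC at a mean of 1 to 5 FPKM. At 100 FPKM or more it was 61.8% and 65.1%. This argues against depth as the cause in contigs at high levels, and depth stays open for low contigs. A few contigs taking most of the FPKM are argued against, since the 10 most abundant contigs held at most 1.58% in a library. Cadmium and the time since the 0 h harvest cannot be told apart, as there were 0 untreated 24 h libraries. A difference in the harvested tissue or hour was not tested, and either could add to the change.

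The third pattern is the appearance of contigs at 24 h: 2986 were listed at 0 in both 0 h libraries and at 1 FPKM or more in both 24 h libraries, against 297 the other way around. With a limit of 5 FPKM these numbers were 339 and 6, and with a limit of 10 FPKM they were 122 and 1. Modestly higher depth at 24 h, within the range searched, is argued against. There, 1 fragment was worth more at 24 h in both lines, with a log2 ratio of at least 0.065, which means less depth. A depth difference too large for the range searched could not be returned and stays open. Another organism in the 24 h material was examined in the same way. In 665 of their 1057 clusters (62.9%), the other contigs summed to at least 1 FPKM in each 0 h library. For these clusters, this argues against an organism whose contigs form clusters of their own. It cannot exclude a related organism whose contigs join ryegrass clusters, and the share among all clusters was not computed. Another organism stays open for the 1444 contigs outside clusters and for the remaining clusters, because the table holds no sequence. Transcripts switched on during the 24 h are the explanation that the design offers, and it was not tested.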

How the results depend on the processing

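All alternatives were fixed before the data were examined; 39 of 84 alternative values lay within 1.5 times the reported count, 45 did not, and for those the cause was not tested beyond what each setting does by construction. Counts are given as higher and lower, in the order LmHC at 24 h, LmLC at 24 h, LmHC over LmLC at 0 h, LmHC over LmLC at 24 h, and difference of responses. With a pseudocount of 5, they were 8369 and 5788, 8438 and 5456, 178 and 739, 366 and 1592, and 685 and 1388, with 9716 contigs shared in direction by the lines' responses (29249 reported) and 253 by the line differences (1755 reported). With a pseudocount of 0.1, the line comparisons grew to 5958 and 7230 at 0 h, 6960 and 8854 at 24 h, and 9345 and 10567 for the difference of responses, with 4821 line differences shared. With no filter, 4762 contigs were higher in LmHC at 24 h, and the difference of responses gave 7474 and 8859. At a mean of at least 5 FPKM, which leaves 26969 contigs, the counts were 6984 and 9356, 7228 and 8405, 381 and 663, 707 and 1165, and 1025 and 1396, with 13201 responses and 447 line differences shared; here lower contigs outnumbered higher ones at 24 h in both lines, as they did with summed clusters (11234 and 13184 in LmHC, 11539 and 11969 in LmLC) and, in LmHC, with a pseudocount of 0.1 (23197 and 24934). Among these 2-fold and shared counts, median-of-ratios scaling moved 1 past 1.5 times, to 11202 contigs lower at 24 h in LmHC; it also moved 8-fold counts past that. Summing clusters, which leaves 42079 features, gave 11234 higher in LmHC and 11539 in LmLC at 24 h, 1105 and 1732 between the lines at 0 h, 1919 and 2733 at 24 h, and 2895 and 3480 for the difference of responses, with 18121 responses and 898 line differences shared. As a share of features, 58.0% changed at 24 h in LmHC with summed clusters, against 55.8% for contigs, and 6.7% against 6.9% differed between the lines at 0 h. LmLC held more of the higher contigs in both line comparisons under each of the 7 alternatives, and the correlation of the responses stayed between 0.82 and 0.91 (Spearman's rho). The lean to LmLC did not hold at every level. At a mean of 100 FPKM or more, 5 contigs were higher in LmHC and 2 in LmLC at 0 h, and 14 and 16 at 24 h. Contigs at least 8-fold higher at 24 h outnumbered those at least 8-fold lower with a pseudocount of 0.1 (10922 and 2232 in LmHC, 11257 and 2251 in LmLC), at a mean of at least 5 FPKM (2489 and 172, 2570 and 203) and with median-of-ratios scaling (4082 and 109, 3813 and 177). Leaving out a library was not possible with 1 library per group. The number of fragments per contig is unknown, so counting error could not be separated from other differences at low FPKM.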

Other observations

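Contigs of an assembly cluster tended to move together at 24 h. Among 10812 clusters with at least 2 expressed contigs, 958 had every expressed member at least 2-fold higher in both lines and 872 had every member at least 2-fold lower in both lines. When the contigs were shuffled among clusters 1000 times, these numbers ranged from 249 to 354 and from 120 to 196. Contigs moving both ways, with at least 1 member higher and another lower in both lines, were found in 414 clusters, against 2652 to 2851 in the shuffles. The hypothesis that contigs of a cluster respond independently of each other, with its prediction written before the count was made, is argued against by this. Contigs of a cluster may be alleles, splice forms or gene copies, so some joint movement could be foreseen. The shuffles were also not matched on level. Because RSEM divides shared fragments among similar contigs, part of the joint movement may come from the counting. The 414 clusters that moved both ways in both lines are candidates for a change of splice form, allele or gene copy at 24 h, which contig sequences would be needed to test. The division of shared fragments could also contribute to movement both ways, and this was not tested.

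Contigs seen at 1 FPKM or more in a single library and listed at 0 in the other 3 numbered 90 for LmHC at 0 h, 391 for LmHC at 24 h, 421 for LmLC at 0 h and 1083 for LmLC at 24 h, with highest values of 4.78, 82.82, 82.08 and 69.12 FPKM. The 683 contigs seen in LmLC alone had a standard deviation of the log2 ratio of 24 h over 0 h (without a pseudocount) of 1.53, against 1.50 for 44327 contigs of LmLC also above 0 in both LmHC libraries. Their medians were 0.06 and -0.50. The sets were not matched on level, so the similar spreads do not show that they behave alike. The 683 contigs had median levels in LmLC of 2.97 FPKM at 0 h and 3.28 FPKM at 24 h. With a pseudocount of 1, the standard deviation between times in LmLC was 1.33 at a mean of 1 to 5 FPKM and 2.49 at 100 FPKM or more.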
